A study of Mus musculus with 6 samples.

How the data were processed

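Primary mouse ADSCs of wild-type genotype were sampled in 2 groups of 3 libraries, control and 48 h Treg co-culture. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was enriched on capture beads and fragmented by heat, and cDNA libraries were built with adapter ligation and bead size selection. Groups and replicate numbers came from the labels, which also give each library a batch from 1 to 3 that the control and co-culture libraries of the same number share.

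The authors deposited 1 table of TPM values, with 1 column per library and 1 row per gene, named by NCBI Gene number. TPM divides reads by gene length and scales each library to the same total, so it keeps no sequencing depth and a rise in abundant transcripts lowers the share of all others. The submitters' processing notes name the builds GRCm38, mm10 and GRCm39 with no role. The aligner, the counting tool and the annotation are not given in the sources used here, and no coordinates are printed for that reason. How reads shared by paralogs were assigned is likewise not given, so near-identical genes carry uncertain separate values. All columns of the table belonged to the 6 libraries.

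Of 22186 gene numbers, 21992 (99.1%) matched a symbol in an NCBI RefSeq gene table of assembly GRCm38.p6, which was used for names only. Unmatched rows held at most 0.064% of the TPM of a library. Each of 10 housekeeping genes was above 0 in every library. In the 15 pairs of libraries at most 60 of 13935 genes above 0 in all libraries had the same value in both. Pairs within a group correlated at 0.996 (Pearson r of log2 values). The columns were thus not copies of each other, and each library was counted as 1 replicate. This check cannot tell libraries of separate cultures from libraries of 1 culture.

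TPM values were put on the log2(TPM + 1) scale, which understates the fold change of low genes. Genes with a mean of at least 1 TPM over all 6 libraries were tested (12405 genes). The main test was limma (version 3.58.1, R 4.3.3; lmFit and eBayes with a mean-variance trend) of Treg co-culture against control without a block, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fold change of at least 2 was counted on the same scale. SE are limma's moderated standard errors. Counts adjusted over the list alone repeat the adjustment within a list. Ifit1 was also tested with an exact permutation of its TPM over the 20 arrangements of the libraries. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

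Before the data were examined, 35 gene lists were fixed (28 pathway or function lists and 7 lists of cell type markers), of which 33 had at least 5 members tested. They were compared with all other genes by limma's camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over the lists), with an estimated correlation and with fry as alternatives. Named genes also followed a rule fixed beforehand. They are Ifit1, the 10 genes with the highest and the 10 with the lowest log2 fold change among genes past the threshold whose groups did not overlap (leaving out unnamed gene models and pseudogenes), up to 4 members per list with the lowest adjusted p, and up to 3 members per marker list with the highest TPM. Genes named outside this rule, including the organ transcripts, were chosen after their values were seen. Some list members are not analysed here, and 1 gene that the rule would name is not reported here.

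The fit with batch as a block was fixed as an alternative, since the labels say that libraries of 1 number share a batch. The deviations of same-numbered libraries from their group means correlated at 0.0115, -0.0146 and 0.00402 for batches 1 to 3, and those of differently numbered libraries between -0.0606 and 0.0653. Other alternatives were pseudocounts of 0.1 and 0.01, no filter or a filter of 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without mitochondrial and ribosomal protein genes, eBayes without the trend or with robust estimation, adjusted p thresholds of 0.01 and 0.1, each library left out in turn, and each batch left out with the block.

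The limma step was tested on simulated data for this comparison with 12405 genes, 100 of them changed by 1 and 100 by 0.3 on the log2 scale. It recovered 96% of the former and 50% of the latter, with 6 false calls (3.95% of all calls). The changed genes were drawn only from the more abundant genes, and the noise was independent between genes. The rates therefore do not cover low genes, correlated genes or a share of changed genes as large as in the data.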

Results

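Messenger RNA was measured by sequencing in primary adipose-derived stromal cells (ADSCs) of wild-type mice. ADSCs are fibroblast-like cells isolated from fat that can be steered towards several mesenchymal lineages. Libraries came from ADSCs kept alone (control, n = 3) and from ADSCs after 48 h of co-culture with regulatory T cells (Treg, the T cell class that restrains immune responses; Treg co-culture, n = 3). The series title names IFIT1, translational suppression and myogenic differentiation. The comparison therefore asks how expression of Ifit1, of translation genes and of muscle genes differed after Treg co-culture. No group was co-cultured with other cells, so an effect particular to Treg cannot be told apart from one of co-culture as such. Values were deposited as TPM, a length-corrected share of all transcripts, for 22186 genes, and the TPM of each library add up to 1000000. Sequencing depth is therefore unknown, and no counting interval can be given. Between 6566 and 7073 genes were listed at 0 per library, and mitochondrially encoded genes took 8.55% to 9.38% of the TPM.

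Interferon-stimulated genes were lower, and muscle and cell cycle genes higher, in the Treg co-culture libraries than in controls. Of 47 type I interferon-stimulated genes tested, 40 fell, and Ifit1 itself dropped from 13.8 ± 1.49 TPM in controls to 4.14 ± 0.282 TPM after co-culture (mean ± SD, n = 3 each). Of 34 skeletal myogenesis genes, 29 rose, among them the muscle-determining transcription factor Myod1 from 22.9 ± 2.52 to 73.2 ± 0.958 TPM and Myog, which drives terminal muscle differentiation, from 105 ± 3.37 to 294 ± 6.56 TPM. Of 58 cell cycle genes, 56 rose, by a list median of 0.51 on the log2 scale. Of 47 collagen and matrix genes 32 fell, as did 15 of 27 cholesterol synthesis genes, though the camera calls of both lists were lost with an estimated correlation (adjusted p = 0.240 and 0.0893).

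In the limma fit on log2(TPM + 1), 4688 of 12405 genes tested passed a Benjamini-Hochberg adjusted p of 0.05, 2454 of them higher and 2234 lower after co-culture. Most of these changes were small, with a median absolute log2 fold change of 0.31, and 191 genes changed at least 2-fold on this scale (118 higher, 73 lower), against 320 with a pseudocount of 0.1 and 336 with 0.01. The 3 co-culture values lay entirely above or below the 3 control values for 49.3% of the genes tested, against 10% by chance. The first principal component held 64.4% of the variance and separated the groups. The second, with 11.5%, separated Treg co-culture 1 (score 14.2) from Treg co-culture 2 (-7.66) and Treg co-culture 3 (-7.31). The labels do not say whether the replicates came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical.

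The largest log2 fold changes upward on the log2(TPM + 1) scale were in the galanin neuropeptide gene Gal (2.27, SE 0.25) and the muscle cadherin Cdh15 (1.96, SE 0.09). They were followed by the actin of heart and developing muscle Actc1 (1.81), the slow and cardiac myosin Myh7 (1.72), the slow troponin Tnnt1 (1.71), the sarcomere-associated Synpo2l (1.70), the leukotriene-forming lipoxygenase Alox5 (1.70), the embryonic myosin Myh3 (1.69), the muscle acetylcholine receptor subunit Chrna1 (1.69) and Myod1 (1.64). Their adjusted p-values in limma ran from 1.97e-10 for Actc1 to 6.94e-05 for Gal. Of these, Gal (0.829 ± 0.709 TPM) and Alox5 (0.302 ± 0.142 TPM) lay below 1 TPM in controls, where the added pseudocount understates a change. By the ratio of mean TPM, Alox5 rose further (10.7-fold) than Gal (9.11-fold) or Cdh15 (4.76-fold).

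On the log2(TPM + 1) scale, the deepest falls were in the neuroendocrine secretory protein gene Scg2 and the potassium channel subunit Kcne4, both at a log2 fold change of -2.27. Kcne4 went from 131 ± 1.21 to 26.4 ± 0.638 TPM. Next came the scavenger receptor Scara5 (-1.82), the R-spondin receptor Lgr5 (-1.70), the elastic fibre protein elastin Eln (-1.69), the small proteoglycan asporin Aspn (-1.68), the receptor gene Gpr165 (-1.62), Ecrg4 (-1.60), the growth factor pleiotrophin Ptn (-1.58) and the secreted Wnt modulator Sfrp2 (-1.56). Ecrg4 had the widest error of the 10 (SE 0.28, adjusted p = 0.00127 in limma). By the ratio of mean TPM, Scara5 fell further (5.42-fold) than Scg2 (5.18-fold) or Kcne4 (4.96-fold).

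**Figure D1:**
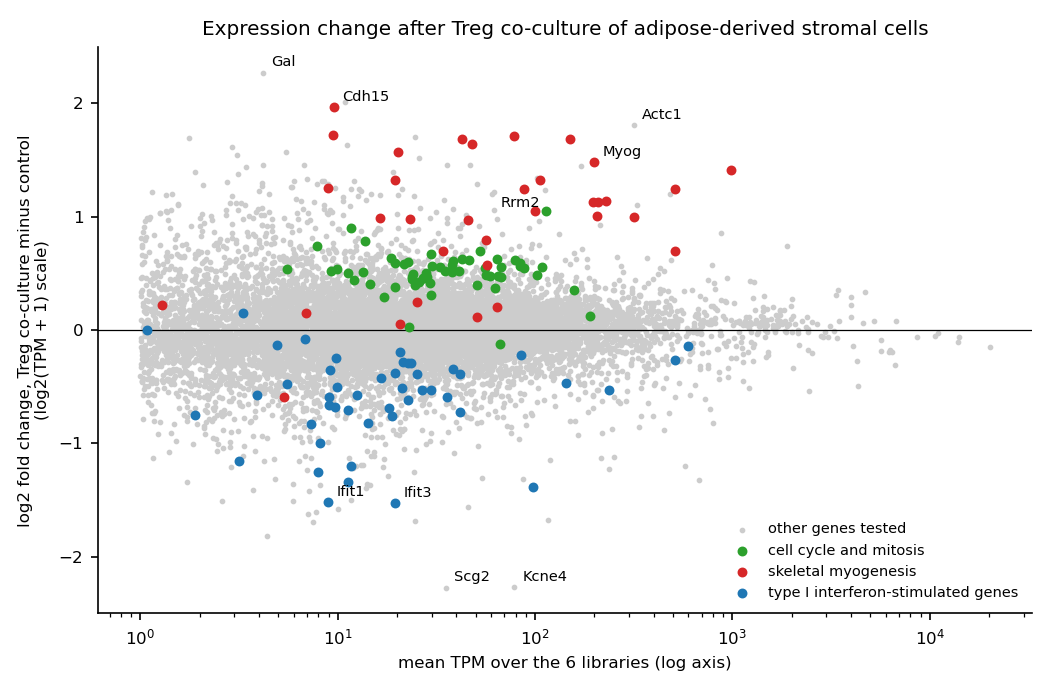
Log2 fold change on the log2(TPM + 1) scale (Treg co-culture minus control, y axis) against the mean TPM over all 6 libraries (x axis, log scale) for the 12405 genes tested, 1 point per gene, with 3 gene lists in colour. Type I interferon-stimulated genes lie mostly below 0 with Ifit1 at -1.52, cell cycle genes lie near 0.51, and skeletal myogenesis genes reach 1.96 (Cdh15).

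Ifit1 encodes an interferon-induced protein that binds viral RNA lacking the host cap modification and blocks its translation. Its TPM were 14.5, 12.1 and 14.9 in controls 1 to 3 and 4.04, 3.93 and 4.46 in Treg co-culture 1 to 3, a 3.34-fold lower mean. The log2 fold change was -1.52 (SE 0.10, limma adjusted p = 1.92e-06). An exact two-sided permutation test of the TPM gave p = 0.1, the smallest p that 3 against 3 libraries allow. The 40 lower members of the type I interferon list (42 adjusted over the list alone) included Ifit3 (-1.53, SE 0.09), the Schlafen family gene Slfn5 (-1.39, SE 0.04) and the secreted glycoprotein gene Lgals3bp (-0.53, SE 0.03), and none of the 47 was higher past the threshold. The list median was -0.53, with an adjusted p of 4.8e-17 in limma's camera test and 0.0315 with an estimated correlation, and the call was lost when the replicate block was added to the latter (0.268). Ifit3 and Ifit3b are near-identical copies, and how reads were shared between them is not given in the sources used here, so their separate values are uncertain.

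Interferon-gamma-induced GTPases and regulators fell less evenly: 17 of 34 were lower and 4 higher (the same counts adjusted over the list alone), and without Treg co-culture 1 the higher count was 2. The list was called lower in camera (adjusted p = 0.0035), with adjusted p = 0.0893 with an estimated correlation. The members with the lowest p were complement genes, namely C1s1 (-0.72), C1ra (-0.73), the C1 inhibitor Serping1 (-0.63) and C3 (-0.68). Of 20 genes for MHC class I antigen processing, 11 were lower and 2 higher (unchanged over the list alone), including the class I light chain B2m (-0.41), the heavy chains H2-K1 (-0.43) and H2-D1 (-0.40) and the peptide-loading factor Tapbp (-0.46). B2m went from 1088 ± 13.4 to 818 ± 33.3 TPM. Its higher count was 1 without control 2, control 3, Treg co-culture 2 or Treg co-culture 3. Camera called this list lower at an adjusted p of 0.00162, with adjusted p = 0.0893 with an estimated correlation. Only 6 MHC class II genes were tested, and the protease gene Ctss (-0.75) was the 1 that fell (also over the list alone; camera adjusted p = 0.491), with 2 lower genes without control 1 and likewise without Treg co-culture 1.

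The 29 skeletal myogenesis genes that rose (30 adjusted over the list alone) spanned transcription factors, fusion genes and sarcomere genes, with a list median of 1.09. The skeletal actin Acta1 went from 536 ± 14.7 to 1428 ± 21.9 TPM, Myh3 from 70.6 ± 1.80 to 229 ± 3.76 TPM and the fast myosin light chain Mylpf from 306 ± 12.4 to 725 ± 6.16 TPM. Control libraries thus already held these transcripts. Below the 1 TPM filter, and named after their values were seen, lay 5 members. Pax7 stood at 0.042 ± 0.0465 TPM in controls and 0.628 ± 0.163 TPM after co-culture and Myf5 at 0.303 ± 0.130 and 0.690 ± 0.185 TPM, while the myosin Myh2 stood at 0.565 ± 0.106 and 0.152 ± 0.0795 TPM, Myh4 at 0.262 ± 0.0715 and 0.535 ± 0.175 TPM and Pax3 at 0.829 ± 0.224 and 1.07 ± 0.545 TPM. With no filter 31 of 39 members were higher and 2 lower. Of the 34 tested in the main fit, the 1 that fell was the growth-restraining Cdkn1c (-0.59), likewise named after its value was seen. Camera gave an adjusted p of 2.37e-20 for the list and 0.0092 with an estimated correlation, but the call was lost when the replicate block was added to the latter (0.157).

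Of 21 cardiac transcription factor and sarcomere genes, 13 rose and 3 fell (the same over the list alone). Actc1 rose 3.52-fold, the cardiac troponin Tnnt2 2.74-fold (91.2 ± 5.11 to 250 ± 4.24 TPM), the atrial and embryonic light chain Myl4 2.00-fold and the calcium store protein Casq2 2.36-fold, and these genes are also active in developing skeletal muscle. The cardiac transcription factors Gata4 (-0.47) and Gata6 (-0.20) and the gap junction gene Gja1 (-0.41), named after their values were seen, were the 3 that fell. The list was called higher (camera adjusted p = 3.55e-05), with adjusted p = 0.111 with an estimated correlation. Without the 5 tested members shared with the skeletal list, an alternative chosen after seeing the data, 8 of 16 rose and 3 fell (adjusted p = 0.00787, and adjusted p = 0.190 with an estimated correlation). Treg co-culture 1 differed from the other libraries in some transcripts of adult heart and liver, chosen after their values were seen. Its Myl2 was 10.9 TPM against at most 0.869 TPM elsewhere, its Myl3 5.30 TPM against at most 0.296 TPM and its albumin transcript Alb 64.9 TPM against at most 0.210 TPM. Without that library 13 genes of the cardiac list were higher and 3 lower of 18 tested.

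**Figure D2:**
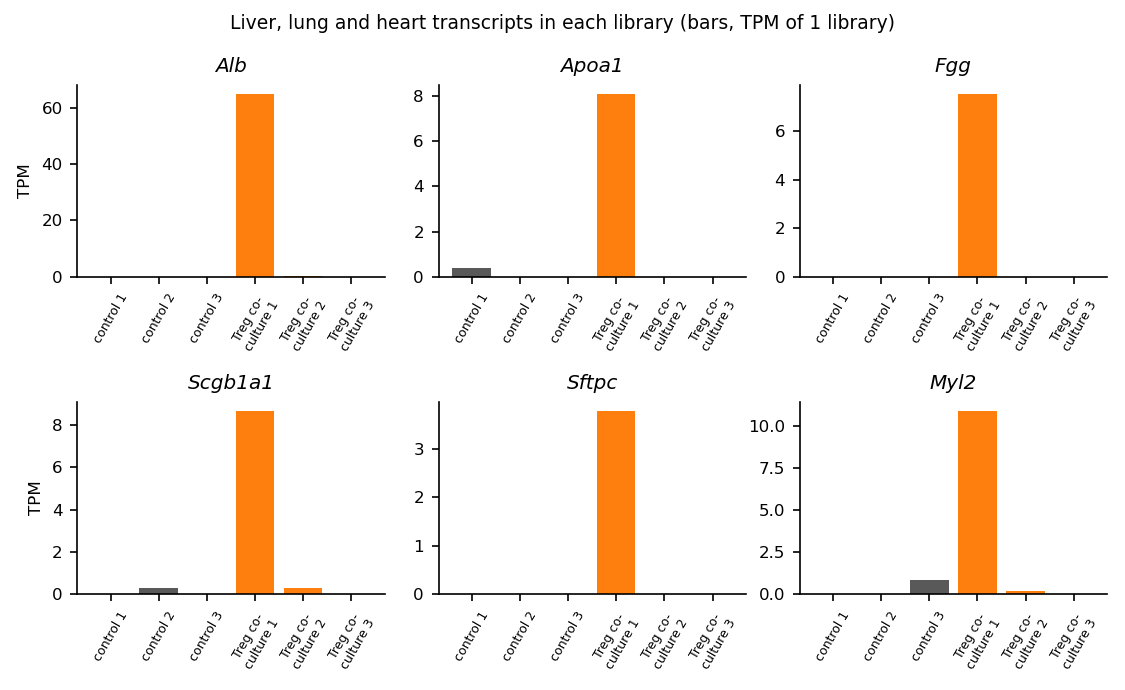
TPM (y axis) of liver (Alb, Apoa1, Fgg), lung (Scgb1a1, Sftpc) and heart (Myl2) transcripts in each of the 6 libraries (x axis), 1 bar per library. Treg co-culture 1 holds 64.9 TPM of Alb and 8.67 TPM of Scgb1a1, and the other 5 libraries hold at most 0.210 and 0.308 TPM.

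Of 27 smooth muscle and myofibroblast contractile genes, 17 rose and 5 fell (18 and 5 over the list alone). The intermediate filament gene Des (1.13), the tropomyosin Tpm2 (0.44) and smooth muscle actin Acta2 (0.22) rose, and the integrin Itga8 fell (-1.19). Camera called the list higher (adjusted p = 0.0108), with adjusted p = 0.362 with an estimated correlation.

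**Figure D3:**
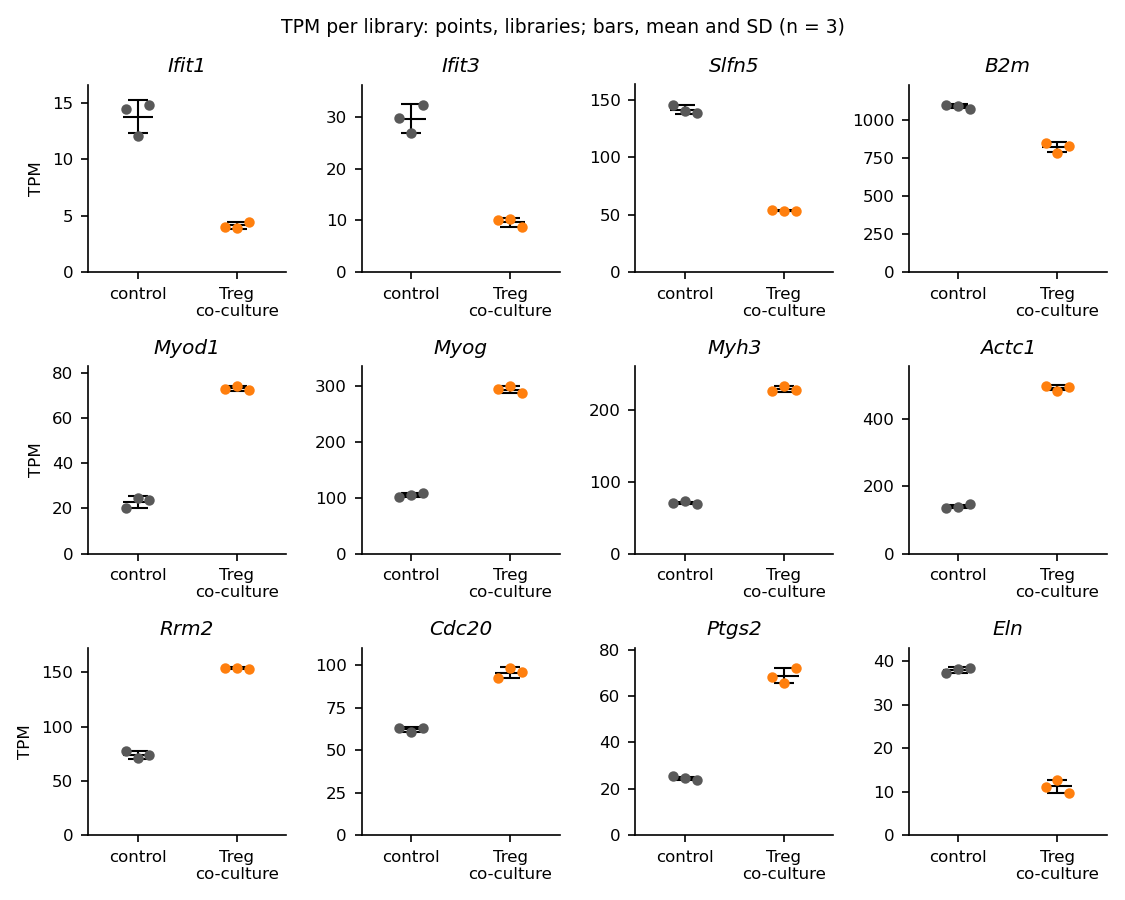
TPM per library (y axis, from 0) for 12 genes in control and Treg co-culture libraries. Points are libraries and bars are the mean and SD of 3 libraries. In each panel the groups do not overlap, as for Myog (105 against 294 TPM) and Ifit1 (13.8 against 4.14 TPM).

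Cell cycle genes moved together. The ribonucleotide reductase subunit Rrm2 went from 74.0 ± 3.57 to 154 ± 0.629 TPM, the mitotic activator Cdc20 from 62.2 ± 1.45 to 95.7 ± 3.09 TPM, and the spindle proteins Prc1 and Tpx2 rose by 0.56 and 0.55 on the log2 scale. Adjusted over the list alone, 56 of 58 rose and 1, Ccnd1, named after its value was seen, fell (-0.13). Adjusted over all genes none was lower, and 1 was without Treg co-culture 2. Camera gave the list an adjusted p of 1.81e-21 and 0.0092 with an estimated correlation, and the replicate block added to the latter ended the call (0.157). Of 28 p53 target and senescence genes, 14 fell and 3 rose (15 and 4 over the list alone). Trp53inp1, a p53-induced cell death gene, fell (-0.85), as did Igfbp3 (-0.29), whereas the kinase Plk2 (0.64) rose. The list was called lower (camera adjusted p = 0.00792), with adjusted p = 0.111 with an estimated correlation.

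Translation genes were examined because the series title names translational suppression, though their transcript levels do not measure translation itself. Of 47 initiation and elongation factors, 22 were higher and 5 lower (23 and 5 over the list alone), among them the cap-binding protein Eif4e (128 ± 2.38 to 156 ± 0.721 TPM), the helicase Eif4a1 (0.26), Eif3b (0.27) and Eif5a (0.36). The list median was 0.09, and camera called it higher (adjusted p = 0.00398), with adjusted p = 0.190 with an estimated correlation. Of 79 cytosolic ribosomal protein genes, 22 were higher and 3 lower (the same over the list alone), with a median of 0.04, Rpsa at 0.12 and Rpl8 at 0.13. That list was not called (camera adjusted p = 0.0653) but passed without control 2 (0.0390) or Treg co-culture 3 (0.0347), where the lower count was 1, and with no filter (0.0438) or by fry (0.0352). Its higher count was 13 without Treg co-culture 1 and likewise without Treg co-culture 2, and Rpl8 lost its call under quantile normalization (log2 fold change 0.01). Chaperones of the endoplasmic reticulum and unfolded protein response genes were higher in 15 of 23 cases and lower in 1 (the same over the list alone), with Hspa5 at 0.28, Hyou1 at 0.39, Hsp90b1 at 0.20 and Manf at 0.34. Camera called this list higher (adjusted p = 0.00792), with adjusted p = 0.198 with an estimated correlation. In the integrated stress response and amino acid synthesis list, which was not called (adjusted p = 0.101), 11 of 32 rose and 5 fell (the same over the list alone). The serine synthesis enzyme Psat1 (0.40), the folate enzyme Mthfd2 (0.42) and the tryptophanyl-tRNA synthetase Wars (0.39) rose and the stress-induced factor Atf5 fell (-0.43).

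Matrix genes were mostly lower. Of 47 fibrillar collagen and matrix genes, 32 fell and 8 rose (33 and 8 over the list alone). Col3a1 went from 5080 ± 98.7 to 3607 ± 36.0 TPM, Col6a1 fell by 0.61 and the proteoglycan decorin Dcn fell by 0.82 on the log2 scale, while the connective tissue growth factor Ccn2 rose (0.85). The list was called lower (camera adjusted p = 7.39e-06), with adjusted p = 0.240 with an estimated correlation. Of 24 matrix metalloproteinase and ADAMTS genes, 4 rose and 9 fell (5 and 9 over the list alone), with the proteases Adamts1 (-0.91), Adamts5 (-0.62) and Mmp2 (-0.57) lower. Its median was 0.04, its mean was -0.02, and camera, which pointed down, did not call it (adjusted p = 0.664). Of 27 TGF-beta responsive genes, 17 rose and 7 fell (the same over the list alone), with Ccn2 and the activin subunit Inhba (0.90) higher and periostin, Postn, lower (-0.54). That list was called higher (adjusted p = 0.00374), with adjusted p = 0.198 with an estimated correlation.

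Secreted signals changed in both directions. The prostaglandin-forming enzyme Ptgs2 went from 24.5 ± 0.727 to 68.9 ± 3.27 TPM, the macrophage growth factor Csf1 rose (0.42), the chemokine Cxcl14 rose (0.84) and the chemokine Cxcl12 fell from 951 ± 21.5 to 585 ± 14.8 TPM. Of 29 NF-kB-driven cytokine and chemokine genes, 10 rose and 5 fell (the same over the list alone). The median (-0.07) and mean (-0.01) of this list were below 0 while camera pointed up, without a call (adjusted p = 0.729). Of 22 immunomodulatory factors of mesenchymal stromal cells, 8 rose and 10 fell (the same over the list alone), with the galectin Lgals1 higher (0.31) and the heme oxygenase Hmox1 lower (-0.46). Here the median was -0.05, the mean 0.02, camera pointed up without a call (adjusted p = 0.962), and without Treg co-culture 1 the lower count was 6. Of 39 angiogenic and trophic factors, 20 fell and 12 rose (21 and 13 over the list alone). The lymphatic growth factor Vegfd went from 799 ± 7.76 to 347 ± 7.29 TPM and the vasodilator peptide gene Adm from 335 to 142 TPM, and the Wnt modulator Sfrp1 fell (-0.73). This list missed the threshold (camera adjusted p = 0.0577) and passed it with the replicate block (0.0471), without Treg co-culture 1 (0.0466), without Treg co-culture 3 (0.0418), without control 3 (0.0410), with no filter (0.0405), with the block without batch 3 (0.0371), with a filter of 5 TPM (0.0209) and by fry (0.000278).

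Markers of the starting cells were lower as a list, with exceptions. Of 30 adipose stromal cell markers, 17 fell and 7 rose (19 and 7 over the list alone). Without control 2, and likewise without control 3, the higher count was 4. The tissue factor gene F3 fell from 1436 ± 8.76 to 1009 ± 8.44 TPM, whereas the intermediate filament nestin, Nes, went from 22.3 ± 0.278 to 71.0 ± 2.16 TPM and the adhesion genes Cd44 (0.58) and Ncam1 (0.73) also rose. The list was called lower (camera adjusted p = 0.0217), with adjusted p = 0.132 with an estimated correlation. Of 25 adipogenic genes, 12 fell and 2 rose (the same over the list alone). Lipoprotein lipase Lpl (-0.76), angiotensinogen Agt (-1.29) and Apoe (-0.80) fell and the transcription factor Klf5 rose (1.17). Camera called this list lower (adjusted p = 0.0032), with adjusted p = 0.132 with an estimated correlation. Osteogenic and chondrogenic genes were not called (adjusted p = 0.545). In that list 4 of 14 rose and 3 fell (the same over the list alone), with osteopontin, Spp1 (1.20), and the osteoblast factor Sp7 (0.91) higher and Omd (-1.42) and Cilp (-0.94) lower.

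Of 76 nuclear-encoded oxidative phosphorylation genes, 23 rose and 1 fell (21 and 1 over the list alone), with cytochrome c, Cycs, at 0.37 and the ATP synthase subunits Atp5g3, Atp5b and Atp5a1 at 0.29, 0.23 and 0.17. The lower count was 3 with the replicate block and without Treg co-culture 2, and 0 without control 1, control 2, Treg co-culture 1 or Treg co-culture 3. The list median was 0.07, and camera called it higher (adjusted p = 0.00445), with adjusted p = 0.0893 with an estimated correlation. Of 13 mitochondrially encoded genes, 7 fell and 1 rose (8 and 1 over the list alone), and the list was not called (adjusted p = 0.149). The lower count was 4 without Treg co-culture 2 and likewise without Treg co-culture 3. COX1 (-0.15), ND4 (-0.09) and CYTB (-0.06) lost their calls under quantile normalization. That step gives genes of equal rank the same value in every library. For genes as abundant as COX1 (21187 ± 423 TPM in controls) it can remove a difference by construction. Cholesterol synthesis genes fell in 15 of 27 cases and rose in none (the same over the list alone), with Hmgcs1 (-0.40), Sqle (-0.42), Insig1 (-0.40) and Sc5d (-0.37). Camera called this list lower (adjusted p = 7.28e-05), with adjusted p = 0.0893 with an estimated correlation.

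The stress lists split by member, and camera called none of these 3. Among 38 hypoxia and glycolysis genes, 13 rose and 11 fell (16 and 13 over the list alone), with the glycolytic genes Hk2 (0.74), Ldha (0.29) and Gapdh (0.29) higher and Adm lower (-1.23). The median was 0.02, the mean was -0.05 and camera pointed up (adjusted p = 0.903). Among 34 immediate early and heat shock genes, 10 rose and 14 fell (11 and 14 over the list alone). Fos went from 77.1 ± 1.70 to 30.6 ± 0.433 TPM and Egr1 from 298 ± 6.91 to 135 ± 4.66 TPM, Zfp36 fell (-0.84) and the mitochondrial chaperonin Hspd1 rose (0.45; list adjusted p = 0.101). Among 30 oxidative stress genes, 13 rose and 11 fell (14 and 12 over the list alone). The thioredoxin reductase Txnrd1 rose from 148 ± 5.26 to 281 ± 7.79 TPM and Gpx1 by 0.61 on the log2 scale, while Hmox1 (-0.46) and the metallothionein Mt2 (-0.34) fell (list adjusted p = 0.975).

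Transcripts of the co-cultured T cells themselves were close to absent from the libraries. Of 45 T cell and Treg markers analysed, 13 were listed at 0 in all 6 libraries, including Cd3e, Cd4, Il2ra and Ctla4, and 39 never reached 2 TPM, with Foxp3, the Treg lineage factor, at most 0.078 TPM. Of 7 tested, 2 were higher and 1 lower (the same over the list alone; camera adjusted p = 0.854). Lef1 (0.520 ± 0.0923 to 2.17 ± 0.625 TPM) and Tcf7 (1.08 ± 0.158 to 2.27 ± 0.475 TPM), which also act in Wnt signalling outside T cells, rose. Lcp1 passed at -0.30 (adjusted p = 0.0389), but not with the replicate block (0.0532), and without control 1, control 2, control 3, Treg co-culture 1 or Treg co-culture 2 the lower count was 0. Values for Ikzf2 were 2.25 ± 0.137 and 2.36 ± 0.305 TPM and for Gimap6 1.91 ± 0.249 and 1.51 ± 0.317 TPM, with adjusted p = 0.823 and 0.307.

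Of 19 monocyte and macrophage markers, 4 fell and 1 rose (2 and 1 over the list alone), with a median of -0.21. Lyz2 fell from 65.9 ± 4.18 to 44.7 ± 6.26 TPM, Lyz1 (-0.58) and Clec4d (-0.54) fell, Ctsc rose (0.31), and Cd68 was 12.8 ± 2.24 and 11.0 ± 2.38 TPM (adjusted p = 0.307). Leaving out 1 library at a time gave 2 lower genes without control 1, control 3, Treg co-culture 1 or Treg co-culture 3, and 1 without control 2. The higher count was 0 without control 2 and likewise without Treg co-culture 3. The list missed the threshold (camera adjusted p = 0.065) but passed it with the replicate block (0.0315), without control 1 (0.0338), without Treg co-culture 2 (0.0258), with the block without batch 2 (0.0259) or batch 3 (0.0175) and by fry (0.0294). Of 13 endothelial markers, 3 rose and 2 fell (3 and 3 over the list alone; camera adjusted p = 0.698), with Tek (-0.36) and Cdh5 (-0.45) lower. The 3 that rose, Kdr (0.27), Sox18 (0.65) and Eng (0.10), numbered 0 or 1 without any 1 of the 6 libraries, and with the replicate block Sox18 (0.0743) and Eng (0.0737) missed the threshold. Flt1 was 11.1 ± 0.642 and 9.46 ± 0.396 TPM (adjusted p = 0.0578). The mesothelial genes Upk3b (-0.32), Lrrn4 (-0.24) and Upk1b (-0.15) fell and the keratin Krt8 rose (0.26), being 3 and 1 of 11 tested in a list that was not called (the same over the list alone, adjusted p = 0.239). These mesothelial genes were abundant in controls, with Upk1b at 247 ± 2.60, Upk3b at 194 ± 4.29 and Lrrn4 at 117 ± 2.49 TPM. Epcam and Cdh1 of the same list reached at most 0.454 and 0.487 TPM in any library. The control cultures thus held mesothelial transcripts at high levels. Of 6 pericyte and Schwann cell markers, Notch3 (-0.94) and Mbp (-0.37) fell and Cspg4 rose (0.73; the same over the list alone, list adjusted p = 0.219). Ebf1 (-0.45) was the 1 B cell marker tested, and no erythroid or neutrophil marker reached the 1 TPM filter.

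**Figure D4:**
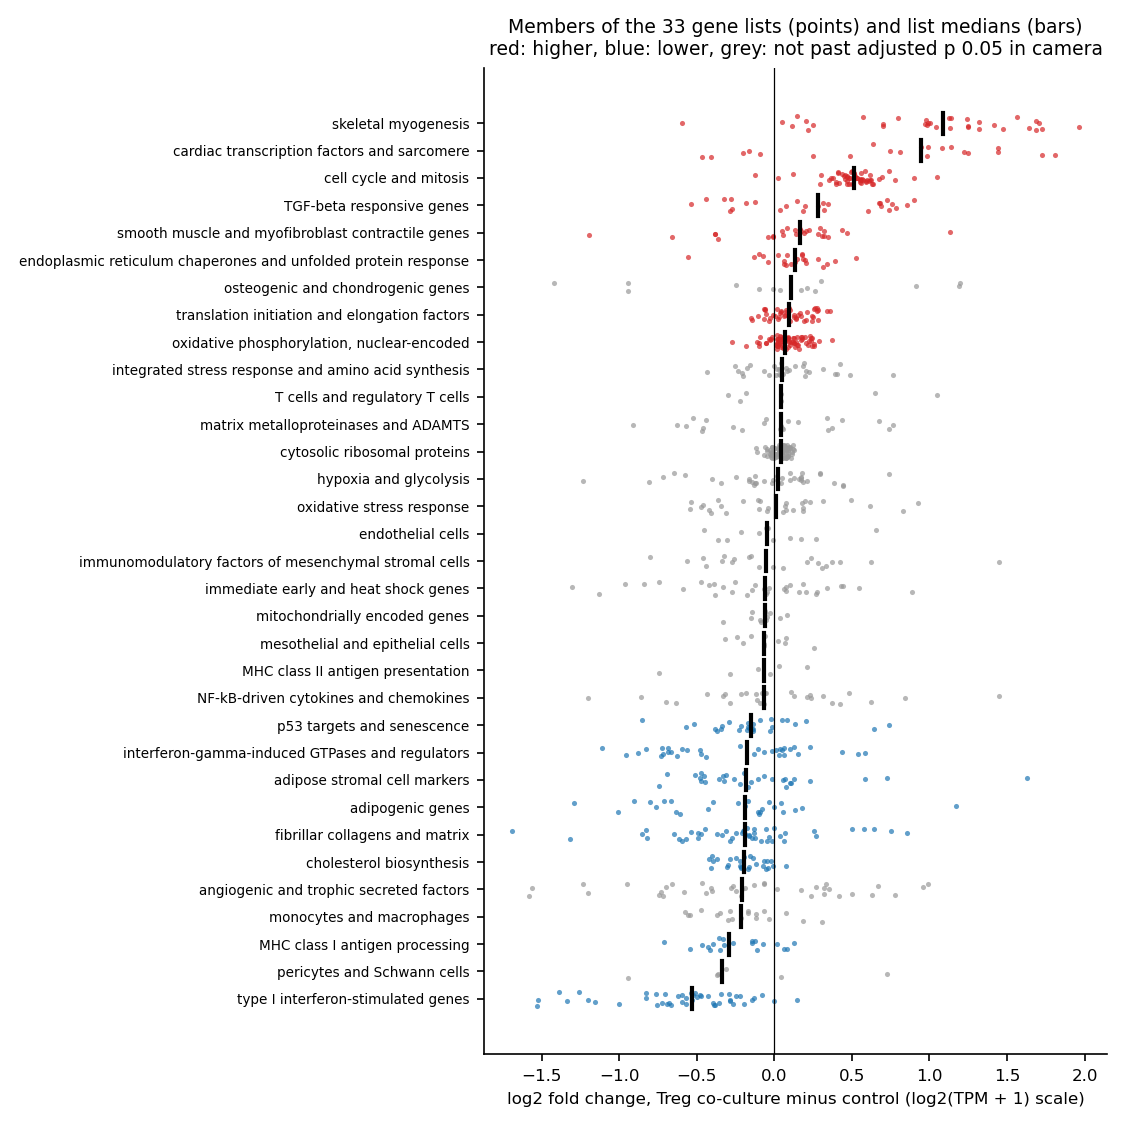
Log2 fold change on the log2(TPM + 1) scale (x axis) of the members of the 33 gene lists tested (y axis), 1 point per gene, with the list median as a black bar. Red lists were called higher and blue lists lower by camera at an adjusted p of 0.05 (8 each), and medians run from -0.53 for type I interferon-stimulated genes to 1.09 for skeletal myogenesis.

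Across the 33 lists with at least 5 members tested, camera called 16, of which 8 were higher and 8 lower. With an estimated correlation 3 calls held, those of the type I interferon-stimulated, skeletal myogenesis and cell cycle lists. With the replicate block and an estimated correlation together, chosen after seeing the data, camera called 0 lists (lowest adjusted p = 0.157), 4 lists lay under an unadjusted p of 0.05, and camera with its preset correlation called 18 in the same fit.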

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

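Alternatives chosen only after the data were seen are the replicate block together with an estimated correlation and the cardiac list without skeletal members. With the replicate block alone, 4492 genes passed, 4333 of them among the 4688 main calls. Among lists and named genes the replicate block changed the calls of 2 lists and 3 genes, given above with their blocked values. Ifit1 stayed past the threshold in all 19 settings, at -1.73 to -1.47, and 2608 of the 4688 genes passed in the same direction in every setting. The count of 4688 fell to 3043 (1626 higher, 1417 lower) at an adjusted p of 0.01. The 191 genes at 2-fold became 320 with a pseudocount of 0.1 and 336 with 0.01, which widen the fold change of low genes. Camera's 8 higher and 8 lower lists became 2 and 1 with an estimated correlation, 0 and 0 when the replicate block was added to it, and 13 and 15 by fry, which asks whether a list's genes move rather than whether they move more than others. Of 16 called lists 15 kept their call in every setting with the preset correlation, and smooth muscle genes missed it with the replicate block without batch 2 (adjusted p = 0.0515). Of 139 named genes past the threshold 122 kept it and 0 reversed. Directions turned only for lists and genes that were not called. Medians where the test turned were -0.026 (no filter), -0.078, -0.089 and -0.131 (without Treg co-culture 1, 2, 3) and -0.071 and -0.135 (replicate block without batch 2, 3) for immunomodulatory factors. For oxidative stress they were -0.038 (no filter), 0.0093 (5 TPM filter), 0.00237 and 0.00827 (without control 1, Treg co-culture 3), and 0.022 and 0.00818 (replicate block without batch 1, 3). Others were osteogenic genes at -0.010 (5 TPM filter), hypoxia genes at 0.0062 (quantile normalization), 0.026 and 0.035 (replicate block without batch 2, 3) and 0.022 (fry), and T cell markers at -0.063 (replicate block without batch 2). Ikzf2 turned to -0.029 without Treg co-culture 1 and -0.047 with the replicate block without batch 1, where Cd68 stood at 0.089. Over single libraries left out Ikzf2 reached 0.087 (without Treg co-culture 2), the oxidative stress median ran from -0.0056 (without Treg co-culture 2) to 0.040 (without Treg co-culture 1), and the immunomodulatory median was highest at -0.047 (without control 2). The cause was not tested. Another scaling moved the median of all genes by under 0.01. TPM keep no depth, so what depth limits cannot be stated.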

Other observations

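The lists of neuromuscular junction, small proteoglycan and Wnt genes and the tests of cell composition, of scaling with genes of like abundance and of organ transcripts were chosen only after the results were seen, and only the other splits were planned. The p-values of the 3 lists are unadjusted, unlike those of the lists fixed beforehand, so they were not held to the same threshold. Genes of the neuromuscular junction, where motor nerves contact muscle, rose with the muscle genes: 8 of 9 tested were higher, with a median log2 fold change of 1.18 (camera unadjusted p = 8.16e-06, and 0.00975 with an estimated correlation). The receptor-clustering protein Rapsn went from 2.26 ± 0.523 to 8.64 ± 1.06 TPM, the fetal receptor subunit Chrng from 14.6 ± 1.11 to 34.3 ± 2.12 TPM (SD, n = 3), the kinase Musk rose by 1.10 on the log2 scale, and Agrn, which neurons and other cells secrete, was the 1 that fell (-0.41). The list was drawn up with the rise of Chrna1 known, and Chrna1 is 1 of its members and also in the myogenesis list.

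Small leucine-rich proteoglycans, which bind collagen fibrils, fell as a family: 10 of 11 tested were lower, with a median of -0.72 (camera unadjusted p = 7.11e-08, and 0.00482 with an estimated correlation). Lum went from 125 ± 3.80 to 49.6 ± 3.25 TPM and Ogn from 433 ± 17.3 to 239 ± 2.99 TPM, and Fmod was 87.6 ± 1.90 and 92.1 ± 5.37 TPM (adjusted p = 0.255 in limma). Among Wnt ligands and secreted Wnt modulators 10 of 17 fell and 2 rose (median -0.48, camera unadjusted p = 0.00115, and 0.0351, likewise unadjusted, with an estimated correlation). The R-spondin gene Rspo1 went from 17.8 ± 0.704 to 5.68 ± 0.834 TPM and Wnt16 from 35.2 ± 2.76 to 18.6 ± 1.25 TPM, and Wnt2 and Dkk2 rose (0.67 and 0.17). Aspn, Sfrp2 and other members were known to be lower when these lists were written.

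Skeletal myogenesis genes were higher after co-culture. A larger share of myogenic cells with an otherwise unchanged profile would raise muscle-only transcripts by 1 common factor, but the log2 ratios of 22 such genes ran from 0.58 (Myh1) to 2.25 (Cdh15), with an SD between genes of 0.388 beyond replicate error (95% bootstrap interval 0.253 to 0.494, median SE of a ratio 0.05). Fewer stromal cells would raise all other cell types alike, yet the 19 monocyte and macrophage markers had a median of -0.215 (SD between markers 0.244) against 1.09 for myogenesis genes (permutation over genes, p = 1e-05, the smallest the permutations can give). That permutation treats genes as independent. Other marker medians were -0.05 (endothelial), -0.06 (mesothelial and epithelial), -0.34 (pericyte and Schwann cell) and 0.04 (T cell). The T cell value rests on the 7 of 45 markers that were tested. Cd3e and Cd4 were at 0 in all 6 libraries, so this value cannot track a share of T cells. Eng of the endothelial list is also in the stromal list. Apart from the T cell value, these medians argue against a rise shared by all other cell types, as far as the markers tested track their cells. They cannot exclude a loss of stromal cells, since co-culture may have changed the other cells too. A scaling would shift genes of like abundance alike, but random sets of genes matched to the members by mean log2 TPM had a median of 0.0061 (95% range -0.07 to 0.08). A response of myogenic cells already present in the control cultures, in which Myog stood at 105 TPM, remains a candidate explanation, as does a changed share together with a changed stage of differentiation, and neither was tested.

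Type I interferon-stimulated genes were lower after co-culture. Random sets of genes matched to the members by mean log2 TPM had a median of -0.0018 (95% range -0.07 to 0.08), which argues against a scaling that shifts genes of like abundance alike. The list median lay below that of the stromal markers (difference -0.349, -0.53 against -0.18, permutation over genes p = 2e-05), but the stromal markers went both ways with an SD of 0.468, so dilution of the stromal cells by other cells stays open. An effect of co-culture on interferon signalling may account for the pattern, and so may a difference in culture handling between the groups, and neither was tested.

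Treg co-culture 1 held more of many liver, lung and heart transcripts. Of 30 hepatocyte markers 96.7% were highest in this library, with a sum of 330 TPM against 121 to 153 TPM in the others. Most of the sum in the others came from Hp and Trf, as in control 1 (64.6 and 81.9 TPM). These transcripts were thus present in all libraries, and the sums understate how far Treg co-culture 1 stood apart in the other hepatocyte markers. The 10 lung epithelium markers added up to 14.9 TPM against at most 1.90 TPM. For heart muscle, 9 of 12 markers were highest in this library. Their sum was 156 TPM, of which Mb gave 99.1 TPM, against 86.7 to 92.4 TPM in controls and 111 TPM in each other co-culture. The 2 that lay above all controls in both other co-cultures, Mb and Ckmt2, are also skeletal muscle genes. Myl2 (0.217 and 0 TPM) and Tnni3 (0.474 and 0.245 TPM) stayed within the range of the controls there. RNA of other organs entering this library, such as at preparation or sequencing, is a candidate source, while for liver a response to co-culture would show in its sister libraries, where 0% of the hepatocyte markers lay above all controls in both. The calls did not rest on this library alone, since 3993 genes passed without it, 3836 of them among the main calls.

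Only 10 ways exist to split the 6 libraries into 3 and 3, too few for a share under 0.05, and in each count below 1 split, the real one, reached the real value. The real split gave 4688 genes, 2454 higher, 2234 lower and 191 at 2-fold, and the highest of the other 9 gave 0 in each (limma). For gene lists the real split gave 8 higher and 8 lower. Among the other splits the highest count in a single direction was 7, or 6 among the splits that part all 3 batches as the real one does. Camera with a preset correlation thus called lists where no gene passed. Each other split, however, sets libraries of both groups on both sides. Part of the real difference stays in its contrast, and the rest widens the spread within its sides. The other splits are therefore no measure of what libraries without a group difference would give.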
